A study of Mus musculus with 4 samples.

How the data were processed

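Total RNA from total thymocytes of 2 Atg16l1 hypomorph and 2 control mice was isolated with a Qiagen column kit, labelled with biotin and hybridised to Affymetrix arrays, 1 array per animal, per the labels' protocols. The deposited values are probe set signals, an intensity on a linear scale, made with GCOS, the Affymetrix array software, per the submitters' processing notes. Its version, scaling target and detection calls are not given in the sources used here. The table held 45101 probe sets, of which 64 Affymetrix control probe sets were left out. Of the 45037 kept, 34945 carried 1 gene symbol, 932 carried several and 9160 carried none in the platform annotation, and genes were named only from probe sets with 1 symbol (18193 genes). Gene order came from the RefSeq gene table of assembly GRCm38.p6, used for names and neighbourhood only, since the deposited table names no genome build. Of the genes named by the arrays, 18142 had a place in it.

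Before analysis the arrays were compared. No pair of arrays shared more than 1 identical value. The 3' cre spike had signals of 9241 and 9499 on the hypomorph arrays and 9361 and 9216 on the control arrays, while median signals ranged from 23.5 to 38.4, so the deposited values had not been brought to a common median. The ratio of 3' to 5' Gapdh signals was 0.797 to 0.817 and that of actin 1.23 to 1.41. As the arrays' median log2 signals spanned 0.66, above a limit of 0.3 set before the data were examined, each array was centred on the common median.

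Values were analysed as log2(signal + 2.29), the pseudocount being the 10th percentile of all signals, so fold changes are on the log2(value + pseudocount) scale and understate the change of dim genes. The 22519 probe sets whose mean over all 4 arrays was at or above the median of such means were tested, covering 10235 genes. Hypomorph and control arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend, two-sided), without covariates, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Sex was not a covariate because the labels do not assign it to arrays. After centring, the tested probe sets still had a median log2 change of 0.18 and the tested genes, each by its brightest probe set, one of 0.21. Changes of gene lists and of their members are therefore given relative to the latter. An exact permutation test of 2 arrays against 2 cannot give a p below 0.333, so the p-values rest on the variance model shared across probe sets.

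Before the data were examined, 31 gene lists were fixed, for autophagy, lysosomes, thymocyte stages, other cell types and stress or metabolic pathways. The 29 lists with at least 5 tested genes were tested with limma's camera at a preset inter-gene correlation of 0.01, with 1 probe set per gene (the brightest), and adjusted over the lists. Of these 11 were called, 3 higher and 8 lower. With an estimated correlation none was, at 1 list with an unadjusted p under 0.05. With the preset correlation camera takes genes as the units, so its p-values do not measure the spread between animals. An estimated correlation and its test rest on the few residual degrees of freedom of 4 arrays, so lists could hardly be called. For the B cell list the estimate was 0.0152, near the preset 0.01, yet the unadjusted p in camera rose from 1.61e-08 to 0.0312. A call lost with an estimated correlation therefore says little about a list. Counts of list members are given over all probe sets and adjusted over the list alone. Both rest on tests against a log2 change of 0, not against the median of the tested genes, so the shift of 0.21 enters them. Genes were named by a rule fixed before the data were examined: Atg16l1, the 12 largest rises and 12 largest falls past the threshold whose groups did not overlap, filled with the smallest unadjusted p where fewer passed and then said not to have passed, and from each list the called members or up to 4 with the smallest p. Not all genes that this rule allows are named.

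The procedures were tested on simulated data with the means and spread of the tested probe sets, in 20 simulations of 2 arrays against 2 with 200 of 22519 probe sets changed. The hypomorph against control fit recovered 3.39% of 1.5-fold, 40.8% of 2-fold and 87.9% of 4-fold changes, and 5.07% of its calls were false. The simulated probe sets varied independently under the variance model that limma assumes. They held neither the shift left after centring nor differences by sex, so the share of false calls on the real arrays may differ. A list of independent genes shifted by 0.25 on the log2 scale among 10235 genes was called in 20 of 20 simulations, with 1 call among the lists that had not been shifted. Changes under 2-fold in single probe sets were thus mostly below what this design can call.

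The alternatives tried were quantile normalization, centring on the tested probe sets, no pseudocount, a pseudocount of 8.44 (the 25th percentile), no filter on dim probe sets, a filter at the 75th percentile, no variance trend, the replicate number as a block, each array left out in turn, other probe sets of a gene, and, for lists, the mean of all probe sets of a gene, an estimated correlation and ranks. Values without centring were added after the data had been seen. Figures were drawn with matplotlib 3.10.9.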

Results

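Gene expression was measured in total thymocytes, the unsorted cells of the thymus, which are mostly developing T cells with small numbers of B cells, macrophages and dendritic cells. The study compared mice carrying a hypomorphic allele of Atg16l1, an allele that leaves the gene with reduced function, with control mice. Atg16l1 encodes a part of the complex that attaches LC3 family proteins to lipid during the formation of autophagosomes. The set held 4 Affymetrix arrays, 2 from hypomorph and 2 from control animals aged 7 weeks. The series text describes the animals as independent of each other and lists 1 male and 1 female per group, and the labels do not say which array is which. The median deposited signal over the 45037 probe sets kept was 38.4 and 27.4 on the hypomorph arrays (replicates 1 and 2) and 23.5 and 27.4 on the control arrays. Over those probe sets the Pearson correlation of log2 signals was 0.927 between the hypomorph arrays, 0.917 between the control arrays and 0.920 to 0.925 between arrays of different groups. The number of arrays, 2 per group, limits the precision of every value.

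Atg16l1 was lower in hypomorph thymocytes. Its main probe set, the brighter of the pair on the array, had deposited signals of 108 and 70.8 on the hypomorph arrays and 184 and 241 on the control arrays. After centring, the mean log2 signal was 6.32 ± 0.10 (SD, n = 2) against 7.90 ± 0.13 (SD, n = 2), a log2 change of -1.57 ± 0.18 (SE) with an adjusted p of 0.0142 in limma. The hypomorph signal was thus 33.6% of the control signal (95% confidence interval 25.4 to 44.4%), or 2.98-fold lower. The other probe set was dim on all 4 arrays, with signals of 7.55, 8.18, 10.7 and 0.445, and was not among the probe sets tested. The call depended on the control arrays: the adjusted p was 0.0751 without control replicate 1 and 0.0893 without control replicate 2, within a range of 0.000107 to 0.876 over all alternatives. Without the filter on dim probe sets the adjusted p was 0.0596, without the variance trend it was 0.274 and on uncentred values it was 0.114, with a log2 change of -1.25. With quantile normalization the log2 change was -1.74 and the adjusted p 0.0375.

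Beside Atg16l1, a small set of genes differed between the groups by several fold. Ctse, which encodes the aspartic protease cathepsin E, rose 16.8-fold after centring (log2 change 4.07 ± 0.19 SE, adjusted p 7.78e-06). Its deposited, uncentred signals were 86.4 and 125 in the controls and 3214 and 1556 in the hypomorphs. Dapk1, a calmodulin-regulated kinase linked to cell death and autophagy, rose 8.36-fold (log2 change 3.06 ± 0.25, adjusted p 0.00110). Ramp1, the accessory protein that gives the calcitonin receptor-like receptor its affinity for CGRP, rose 5.77-fold on 1 probe set (adjusted p 0.00111). Gnb4, a G protein beta subunit, was 5.47-fold lower (log2 change -2.45 ± 0.29, adjusted p 0.0142). In all, limma called 14 of 22519 tested probe sets at an adjusted p under 0.05, 11 higher and 3 lower in the hypomorphs, and 3624 probe sets had an unadjusted p under 0.05, of which 3355 were higher. The latter count depended on scaling, at 1558 with quantile normalization and 1693 with each array centred on the tested probe sets. The tested genes had a median log2 change of 0.21, so that changes relative to that median were 3.86 for Ctse, 2.85 for Dapk1, 2.32 for Ramp1, -2.66 for Gnb4 and -1.78 for Atg16l1. With quantile normalization 4 probe sets passed, those of Ctse, Dapk1, Ramp1 and Atg16l1, and with each array centred on the tested probe sets 7 passed, 4 higher and 3 lower. Without the variance trend no probe set passed, at 2492 with an unadjusted p under 0.05.

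The remaining called genes rose by smaller factors. Ptov1 rose 4.50-fold, Mgat5, which encodes an enzyme that branches N-linked glycans, rose 2.48-fold, Kif22, a kinesin that binds chromosomes in mitosis, rose 1.92-fold, and Pan3, a subunit of a deadenylase that shortens mRNA tails, rose 1.90-fold. Their adjusted p-values in limma were 0.0267, 0.0233, 0.0446 and 0.0440, and none of these 4 calls held under quantile normalization. With the replicate number as a block the adjusted p was 0.0713 for Ptov1, 0.0713 for Kif22 and 0.0651 for Pan3, while Mgat5 stayed called (0.0355). Another 3 of the higher probe sets carry several symbols, all of the haemoglobin alpha or beta family, and rose 2.21- to 2.72-fold with adjusted p-values of 0.00655 to 0.0233. Leaving out an array ended the calls of these 4 genes, while their log2 changes stayed within 2.02 to 2.32 for Ptov1, 1.08 to 1.53 for Mgat5, 0.84 to 1.03 for Kif22 and 0.83 to 1.02 for Pan3: without control replicate 1 the adjusted p was 0.0884 for Ptov1, 0.0906 for Mgat5, 0.159 for Kif22 and 0.138 for Pan3, and without control replicate 2 it was 0.0659, 0.0584 and 0.150 for Ptov1, Kif22 and Pan3. Without hypomorph replicate 2 that of Ptov1 was 0.0657. For each of the 11 called probe sets with 1 gene symbol, the signals of the groups did not overlap. Complete separation of this kind arises by chance in 33.3% of unchanged probe sets with 2 arrays against 2.

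**Figure D1:**
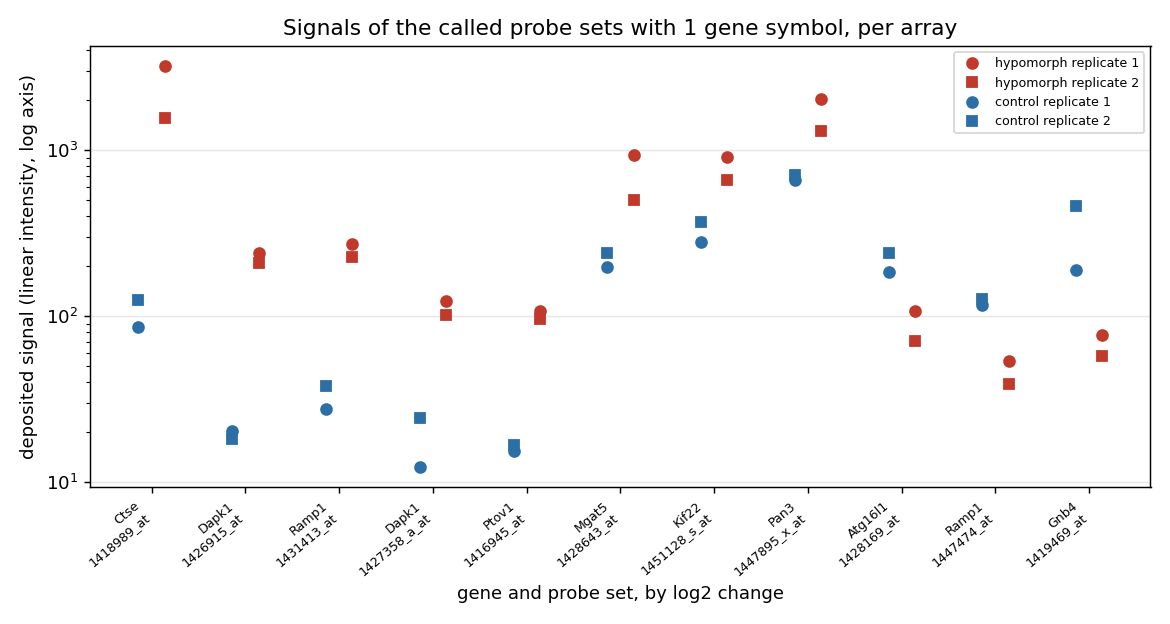
Deposited signal (linear intensity, log axis) of each called probe set with 1 gene symbol on each of the 4 arrays, hypomorph in red and control in blue, ordered by log2 change from Ctse (4.07) to Gnb4 (-2.45). The 2 hypomorph arrays lie on 1 side of the 2 control arrays for each probe set, and Ramp1 appears with 1 probe set higher and 1 lower.

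Probe sets of the same gene did not all move alike. Both Dapk1 probe sets were called, the second at a log2 change of 2.20 (adjusted p 0.0390, and 0.253 with quantile normalization). Of 3 tested Ramp1 probe sets, 1 rose (log2 change 2.53), 1 fell (-1.70, adjusted p 0.0233, and 0.0825 with quantile normalization) and the third was at 0.28 (adjusted p 0.364). The other Ctse probe set was at -0.42 (adjusted p 0.591), the other Gnb4 probe set at -1.04 (adjusted p 0.196) and the other Mgat5 probe set at 0.49 (adjusted p 0.247). The other Ptov1 probe sets were at 0.49 and 0.27, those of Kif22 at 0.75 and 0.42, and those of Pan3 between -0.07 and 0.13, none past the threshold.

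Several further genes had small unadjusted p-values without passing the adjusted threshold. On the higher side these were Pcbd2 (log2 change 1.77), Zfp958 (1.42), the kinetochore genes Cenph (1.25) and Ndc80 (0.84), and Shcbp1 (0.75), with adjusted p-values in limma of 0.0703 to 0.114. On the lower side Stk25, a kinase of the Ste20 family, was at -1.35 (adjusted p 0.0550), followed by Pou6f1 at -1.09, D2hgdh, a mitochondrial dehydrogenase, at -1.01, and Cdk5rap1 at -0.94, with adjusted p-values of 0.0964 to 0.153. Lpcat4 (-1.07), Prag1 (-0.63), the chemokine receptor gene Cxcr3 (-0.87), Lgals3 (-0.70), Thegl (-1.29) and the retinal arrestin gene Sag (-1.20) had adjusted p-values of 0.196 to 0.222. Without hypomorph replicate 1 the log2 change was 2.26 for Pcbd2, 1.48 for Zfp958, 1.16 for Cenph, 0.85 for Ndc80, -1.58 for Stk25, -0.94 for Pou6f1 and -1.16 for Cdk5rap1. Without hypomorph replicate 2 it was 1.28 for Pcbd2, 1.35 for Cenph, -1.13 for Stk25, -1.23 for Pou6f1 and -1.22 for D2hgdh. With all arrays the other probe set of D2hgdh was at 0.18. Each of these fits holds a single hypomorph array, so it has no spread between hypomorph animals. In the gene order of the reference annotation, Ramp1, Stk25, D2hgdh, Mgat5 and Ctse lay 25, 56, 62, 137 and 172 places from Atg16l1 on the same chromosome.

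**Figure D2:**
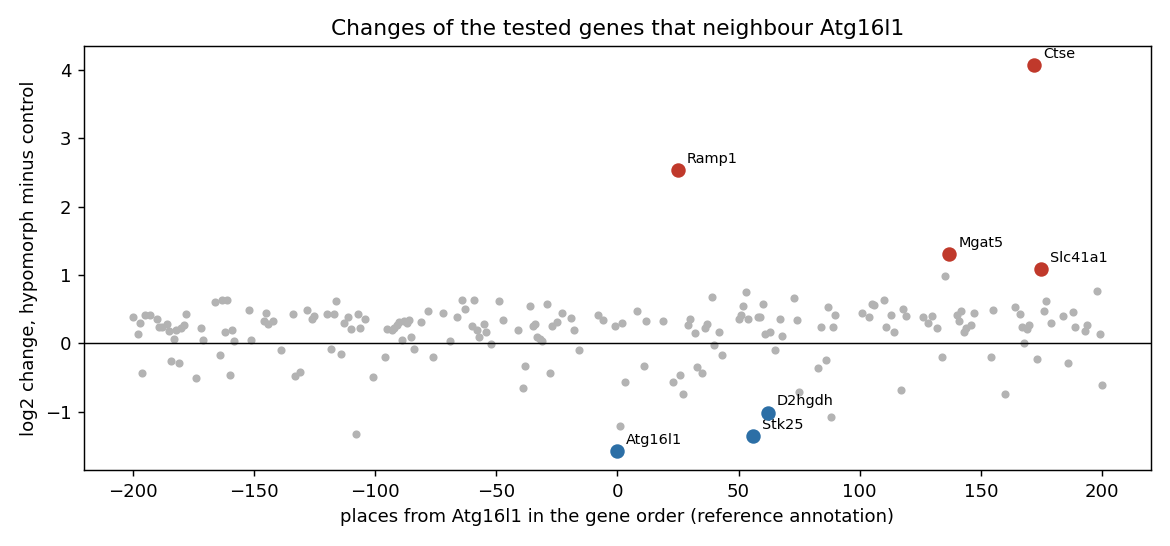
Log2 change (hypomorph minus control) of the tested genes within 200 places of Atg16l1 in the gene order of the reference annotation, with the strongest probe set of each gene. Large coloured points are genes with p under 0.001 after multiplication by the gene's number of tested probe sets, a limit chosen after the values were seen: Ramp1, Mgat5, Slc41a1 and Ctse above 0, and Atg16l1, Stk25 and D2hgdh below 0.

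Cell cycle genes were higher as a group. Of 31 tested genes of the list, 26 lay above the median change of the tested genes, and their mean was 0.27 above it on the log2 scale. Bub1b, Bub1 and Cenpf, which act at the kinetochore and in the spindle checkpoint, were at 0.58, 0.49 and 0.52 above the median, and Birc5, a chromosomal passenger protein, at 0.49. None of the 31 passed over all probe sets. Adjusted over the list alone, and tested against a change of 0 and not against that median, 26 were higher, a number that was 14 (with 1 lower) with quantile normalization. Not relative to that median, the log2 changes of Bub1b, Bub1 and Cenpf were 0.79, 0.70 and 0.73. Without hypomorph replicate 1 they were 0.87, 0.75 and 0.77. Camera called the list with a preset correlation between genes (adjusted p 8.94e-12). It was not called with an estimated correlation (adjusted p 0.416, within a range of 1.63e-15 to 0.416 over all alternatives). The former p-value takes genes as the units and does not measure the spread between animals. The estimated correlation, from so few arrays, could hardly call any list. The same limits hold for the camera p-values of the lists below.

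Markers of antigen-presenting cells were lower as groups relative to the tested genes. Of 14 dendritic cell and MHC class II genes, 13 lay below the median, with a mean of -0.41. Cd74, the invariant chain of MHC class II, was at -0.54, H2-Aa, an MHC class II alpha chain, at -0.46 and the chemokine gene Ccl17 at -1.20. Of 11 B cell and plasma cell genes, 10 lay below the median, with a mean of -0.43, among them Ms4a1 (-0.84), which encodes CD20, the B cell receptor component Cd79a (-0.84) and Cd22 (-0.69). None of these genes passed singly, over all probe sets or adjusted over the list alone, and with quantile normalization 3 of the first list and 1 of the second were lower when adjusted over the list alone. Camera called both lists with the preset correlation (adjusted p 5.26e-08 and 1.56e-07), and neither was called with an estimated correlation (adjusted p = 0.416 for each, the highest over all alternatives, the lowest being 1.45e-10 and 7.95e-08). Without control replicate 1 the mean of the dendritic cell list was -0.26. On uncentred values, where each probe set is moved by the same 0.33, Cd74 and H2-Aa had log2 changes of 0.00 and 0.08, where the median log2 change of all tested probe sets was 0.51.

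Macrophage and granulocyte genes had a mean of -0.25 relative to the tested genes, with 13 of 19 below the median. The macrophage genes Csf1r (-0.75) and C1qa (-0.78) had the smallest p-values, and none of the 19 passed singly, over all probe sets or adjusted over the list alone. The list was called with the preset correlation (adjusted p 6.14e-06) but not with an estimated one (adjusted p = 0.416 with an estimated correlation, within a range of 5.16e-16 to 0.840). It rested on control replicate 2, since without that array the mean was 0.12 and the adjusted p 0.840, and without hypomorph replicate 2 they were -0.09 and 0.0672. Granulocyte genes of the list, chosen here after their values were seen, were lowest on control replicate 1: S100a8 had signals of 1401 and 1760 on the hypomorph arrays, 263 on control replicate 1 and 2723 on control replicate 2, and S100a9 had 827, 1034, 126 and 1607.

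Among T cell lists, regulatory and innate-like T cell genes had a mean of -0.28, with 13 of 16 below the median. The cytotoxic granule gene Nkg7 was at -0.73, the transcription factor genes Tbx21 and Maf at -0.82 and -0.69, and none passed singly. The list was called with the preset correlation (adjusted p 6.69e-05; adjusted p = 0.416 with an estimated correlation), within a range of 2.14e-05 to 0.416. Genes of double-negative thymocytes, the earliest T cell precursors in the thymus, had a mean of -0.23 with 11 of 16 below the median (adjusted p 0.0122; adjusted p = 0.416 with an estimated correlation), within a range of 0.00213 to 0.416, where Hhex was at -0.81 and Kit at 0.56. The double-negative list was not called with quantile normalization (adjusted p 0.124), without hypomorph replicate 2 (mean -0.16, adjusted p 0.0941) or without control replicate 1 (mean -0.13, adjusted p 0.290), and no member of either list passed, also when adjusted over the list alone. The lists for double-positive thymocytes (mean -0.12, adjusted p 0.161), mature single-positive thymocytes (-0.15, adjusted p 0.0949) and positive selection and T cell receptor signalling (-0.06, adjusted p 0.764) were not called. Without hypomorph replicate 2 the single-positive list had an adjusted p of 0.00352, within a range to 0.996, and it was also called with quantile normalization (0.00841), with centring on the tested probe sets (0.0465), with the filter at the 75th percentile (0.0232) and with the mean of all probe sets (0.0318). The double-positive list was called with centring on the tested probe sets (adjusted p 0.0471) and with the filter at the 75th percentile (0.00318), within a range to 0.976. Among their members Cxcr4 was at 0.23, Cd69 at 0.11 and Egr2 at 0.24, each with an adjusted p above 0.05.

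The remaining called lists moved less or lost their call more easily. Ribosomal protein genes had a mean of -0.21 with 18 of 19 below the median (adjusted p 0.000840; adjusted p = 0.692 with an estimated correlation), and with quantile normalization the mean was 0.00 and the adjusted p 0.558, within a range of 4.67e-14 to 0.692. Without hypomorph replicate 1 the mean was -0.11 (adjusted p 0.670) and without control replicate 1 it was -0.12 (adjusted p 0.143). Rpl19 was at -0.34 and Rpl14 at 0.03, and relative to genes of like signal the median of the 19 was -0.02. Mitochondrial respiration genes had a mean of 0.05 with 18 of 27 above the median (adjusted p 0.0204; adjusted p = 0.699 with an estimated correlation), with the succinate dehydrogenase gene Sdhc at 0.49 and the mitochondrial transcription factor gene Tfam at 0.21. Sdhc was higher when adjusted over the list alone. Its log2 change, not relative to the median, was 0.70 with all arrays and 0.75 without hypomorph replicate 1. Glycolysis and hypoxia genes had a mean of 0.08 with 15 of 20 above the median (adjusted p 0.0344; adjusted p = 0.464 with an estimated correlation), among them Tpi1 (0.29) and Pdk1 (0.24). Interferon response genes had a mean of -0.13 with 18 of 26 below (adjusted p 0.0315; adjusted p = 0.692 with an estimated correlation), although Oas1a was at -0.88 and Oasl2 at 0.70. Pancreas and skeletal muscle genes, markers of tissues other than thymus, had a mean of -0.37 over 5 genes (adjusted p 0.0309, and 0.692 with an estimated correlation). The dim pancreas genes Cela1 and Cela3b were at -0.95 and -0.67 and the muscle gene Mylpf at 0.16. These last 4 calls were lost with quantile normalization, at adjusted p-values of 0.0748 for mitochondrial respiration and for glycolysis and hypoxia, 0.0585 for interferon response and 0.235 for pancreas and skeletal muscle. With all arrays no member of the 5 lists passed over all probe sets, and only Sdhc did when adjusted over the list alone.

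Leaving out single arrays also ended these calls. Mitochondrial respiration, with a mean of 0.05 on all arrays, had a mean of 0.01 (adjusted p 0.168) without hypomorph replicate 2, 0.04 (adjusted p 0.271) without control replicate 1 and 0.06 (adjusted p 0.120) without control replicate 2, within a range of 0.000114 to 0.699. Glycolysis and hypoxia, at 0.08 on all arrays, had a mean of 0.0076 (adjusted p 0.438) without hypomorph replicate 1, 0.11 (adjusted p 0.0797) without control replicate 1 and 0.05 (adjusted p 0.282) without control replicate 2, within 0.00128 to 0.464. The interferon response mean was 0.02 without hypomorph replicate 2 and 0.04 without control replicate 1, and the call was lost in both. The log2 change of Oas1a, not relative to the median, was -0.67 with all arrays and -1.11 without hypomorph replicate 1. Pancreas and skeletal muscle had a mean of -0.38 (adjusted p 0.0880) without hypomorph replicate 1, -0.36 (adjusted p 0.0611) without hypomorph replicate 2 and -0.29 (adjusted p 0.288) without control replicate 2, within 0.00524 to 0.692.

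**Figure D3:**
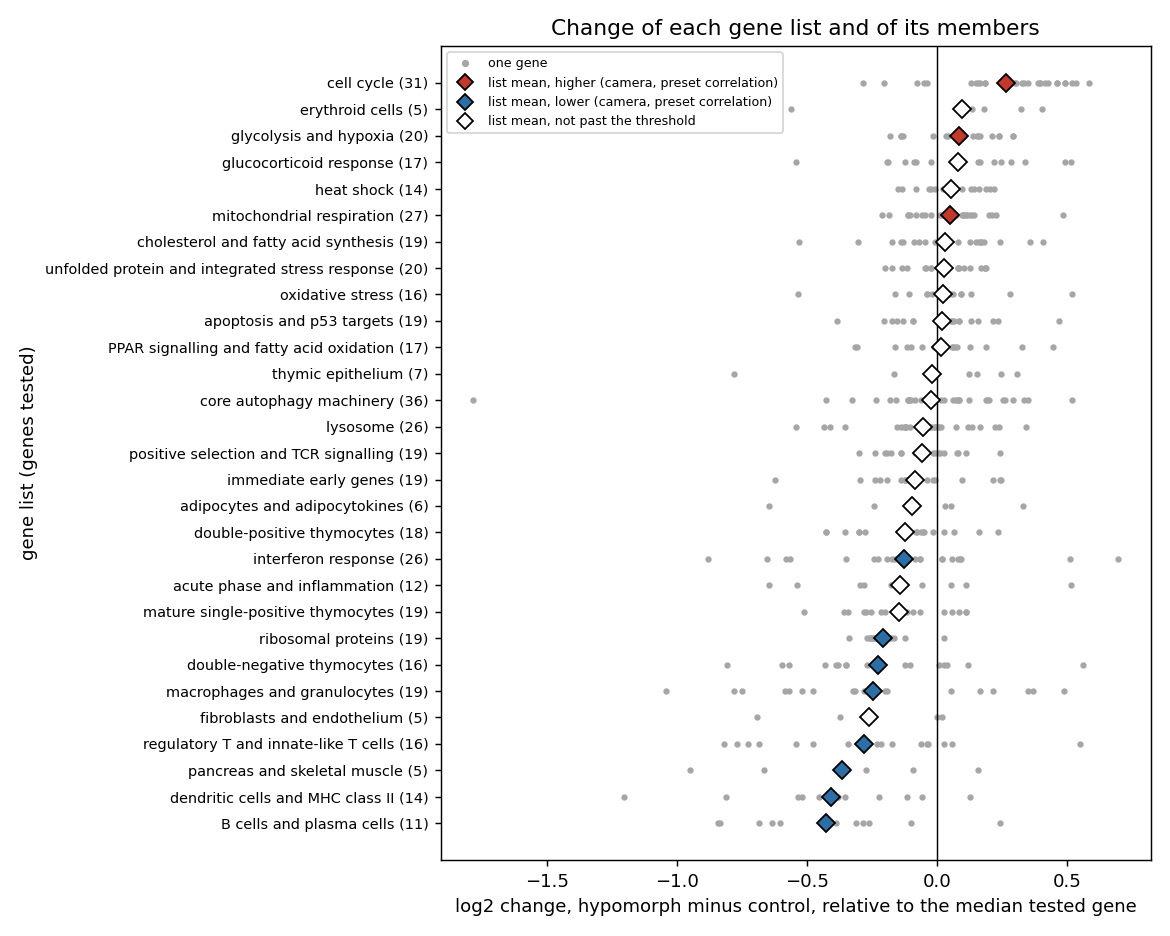
Log2 change (hypomorph minus control) relative to the median tested gene, for each tested gene of each list (grey points) and for the mean of the list (diamonds), with the number of tested genes in brackets. The cell cycle list has the highest mean (0.27) and the B cell (-0.43) and dendritic cell and MHC class II (-0.41) lists the lowest, and filled diamonds mark lists called by camera with the preset correlation, none of which was called with an estimated correlation.

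Core autophagy genes other than Atg16l1 did not pass. Of the 36 tested, 1 was called, Atg16l1 itself, and 35 were not. The mean of the list was -0.02 and its median -0.01 relative to the tested genes, while camera gave the direction up (adjusted p 0.764). Lysosomal genes had a mean of -0.05 (adjusted p 0.797), with the proton pump subunit gene Atp6v1a at 0.24. Lists of adipocyte genes (-0.10, adjusted p 0.502), PPAR signalling and fatty acid oxidation (0.02, adjusted p 0.764), and acute phase and inflammation (-0.14, adjusted p 0.0593) were not called. Within the first 2 of these, Acp5 at 0.33 and Fabp5 at 0.44 were higher when adjusted over the list alone. The log2 change of Fabp5, not relative to the median, was 0.66 with all arrays and 0.78 without hypomorph replicate 1. Without the filter on dim probe sets the autophagy list had a mean of 0.04 and an adjusted p of 0.0269, within a range to 0.988, and the adipocyte list a mean of -0.38 and an adjusted p of 0.0464, within a range to 0.971. The acute phase list was called with the pseudocount at the 25th percentile (adjusted p 0.0442), without the variance trend (0.0468) and on ranks (0.0394), within a range to 0.464.

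None of the other lists was called with the main settings. Their means were 0.03 for cholesterol and fatty acid synthesis (adjusted p 0.591), where Insig1 was at 0.41, 0.03 for the unfolded protein and integrated stress response (adjusted p 0.259), where Herpud1 was at 0.19, and 0.05 for heat shock (adjusted p 0.0616), where Hspd1 was at 0.22. They were 0.02 for oxidative stress (adjusted p 0.473), 0.02 for apoptosis and p53 targets (adjusted p 0.423), with Bbc3 at 0.47, 0.08 for the glucocorticoid response (adjusted p 0.544), with Fkbp5 at 0.34 and higher when adjusted over the list alone, and -0.08 for immediate early genes (adjusted p 0.259), with Btg2 at -0.62. Fibroblast and endothelial genes had a mean of -0.26 over 5 genes (adjusted p 0.0885). Thymic epithelial genes had a mean of -0.02 and a median of 0.12 over 7 genes (adjusted p 0.423), with Ly75 at 0.25. Erythroid genes with a probe set of their own had a mean of 0.10 over 5 genes (adjusted p 0.957), with Bpgm at 0.32, beside the haemoglobin probe sets that rose. The Paneth cell list, with 2 tested genes, and the sex-linked list, with 4, were too small to test. Without hypomorph replicate 2 the mean was 0.14 for heat shock, 0.10 for the unfolded protein response and -0.46 for fibroblasts and endothelium. The log2 change of Fkbp5, not relative to the median, was 0.55 with all arrays and 0.62 without hypomorph replicate 1. Without the filter on dim probe sets cholesterol synthesis and oxidative stress (adjusted p 0.0417 each), apoptosis (0.0464), heat shock (0.0240) and fibroblasts and endothelium (0.00630) were called, and with the filter at the 75th percentile immediate early genes were (0.0296). Heat shock was also called with the pseudocount at the 25th percentile (0.0300) and with the mean of all probe sets (0.0286).

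The arrays also differed within groups. Xist, expressed from the inactive X chromosome, had signals of 47.7 and 3434 on hypomorph replicates 1 and 2 and of 29.2 and 2915 on control replicates 1 and 2. The Y-linked genes Eif2s3y and Kdm5d, like Xist from the sex-linked list, had signals of 703 and 250 on hypomorph replicate 1, 4.52 and 4.61 on hypomorph replicate 2, 461 and 152 on control replicate 1, and 3.43 and 0.659 on control replicate 2. Leaving out an array moved the count of calls. It was 340 without hypomorph replicate 1, 58 without hypomorph replicate 2, 8 without control replicate 1 and 22 without control replicate 2, against 14 with all arrays. The 340 come from a fit in which hypomorph replicate 2 was the only hypomorph array, and 14 of them were the probe sets called with all arrays and 49 stood apart on hypomorph replicate 2 alone. In 261 of them hypomorph replicate 1 had moved less than 50% as far in the same direction, a share that calling on the other hypomorph array alone favours.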

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

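The values without centring ("as deposited") were chosen after the data had been seen, and the other alternatives before. Against 14 called probe sets (11 higher, 3 lower), quantile normalization called 4 (3 higher, 1 lower), all among the 14, centring on the tested probe sets 7 (4 higher, 3 lower), no filter on dim probe sets 4 (4 higher, 0 lower), and no variance trend 0 (0 higher, 0 lower), at 2492 with an unadjusted p under 0.05 in limma. Uncentred values gave 84 (73 higher, 11 lower), and leaving out an array 8 to 340 (7 to 222 higher, 1 to 118 lower), where the lone array of a group is assumed to vary like the pair of the other group. The replicate numbers are not labelled as pairs, and the deviations of same-numbered arrays correlated at 0.0819 over probe sets. With the number as a replicate block 9 were called (7 higher, 2 lower), and Ptov1 (adjusted p 0.0713), Kif22 (0.0713) and Pan3 (0.0651) were not among them. In both groups Xist was high on the replicate 2 array and the Y-linked genes Eif2s3y and Kdm5d were high on the replicate 1 array. A block by number thus also divides the arrays by these sex-linked signals, and the series text lists 1 male and 1 female per group. The cause of the other differences was not tested.

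For Atg16l1 the log2 change was -1.57 both with no filter (adjusted p 0.0596) and with no variance trend (adjusted p 0.274), -1.25 uncentred (adjusted p 0.114) and -1.66 to -1.48 with an array left out, and its dim other probe set gave 0.44 (adjusted p 0.876). The gene passed under 7 of 13 alternatives. The number of gene lists called, 11 with the main settings, was 6 with quantile normalization, 0 with an estimated correlation and 6 to 10 with an array left out. Over all alternatives, named genes kept direction and side of the threshold in 767 cases, lost a call in 45, gained one in 23 and changed sign in 10, and gene lists did so in 358, 45, 22 and 32. Most of these genes and lists had no call to lose with the main settings, so the counts of 767 and 358 do not measure how stable the calls were. Signal over background limits the dim probe sets, whose fold changes the pseudocount understates.

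Signs changed on other probe sets for Ctse (-0.42), Ramp1 (-1.70), Pan3 (-0.073 and -0.015), D2hgdh (0.18) and Btg2 (0.30), and uncentred for Cd74 (0.0029), H2-Aa (0.083) and Rpl19 (0.20), where leaving out centring adds the same 0.33 to each probe set. Rpl19 also ranged from -0.31 to 0.055 with an array left out. Among the lists, thymic epithelium was at 0.11 with quantile normalization, 0.0025 with no pseudocount and 0.026 with the mean of all probe sets, and ribosomal proteins at 0.0010 with quantile normalization. With no filter, core autophagy was at 0.040, positive selection and TCR signalling at 0.0046, erythroid cells at -0.16 and the unfolded protein response at -0.022. With the filter at the 75th percentile cholesterol synthesis was at -0.00066 and oxidative stress at -0.027, and thymic epithelium, erythroid and B cells and 4 other lists had too few genes.

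With an array left out the lists that changed sign ranged from -0.14 to 0.15 (thymic epithelium), -0.066 to 0.014 (core autophagy), -0.16 to 0.036 (positive selection), -0.033 to 0.23 (erythroid cells), -0.054 to 0.099 (unfolded protein response), -0.037 to 0.088 (cholesterol synthesis), -0.027 to 0.11 (oxidative stress), -0.040 to 0.14 (heat shock), -0.040 to 0.033 (apoptosis), -0.081 to 0.12 (PPAR signalling), -0.29 to 0.036 (interferon response), -0.034 to 0.16 (glucocorticoid response) and -0.61 to 0.12 (macrophages and granulocytes).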

Other observations

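Of the tests below, those of array brightness for the cell cycle genes and for the cell markers were chosen before their results were seen, and the others, with their limits and windows and the predictions from each pair of arrays alone, after.

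Single arrays held genes that stood apart from the other 3 arrays, by a log2 gap of at least 2 where those 3 lay within 1 of each other, all named here after their values were seen. Hypomorph replicate 2 held 49 such probe sets, 34 lower and 15 higher, against 2 on hypomorph replicate 1, 9 on control replicate 1 and 5 on control replicate 2. Dzip1, a gene of primary cilia, had a signal of 5.94 on hypomorph replicate 2, against 1046 on the other hypomorph array and 742 and 801 on the control arrays. Rab6b, a small GTPase of the Golgi, had 1.79 against 249, 216 and 231, and Bfar, an apoptosis regulator, had 2.35 against 387, 170 and 250. The nonclassical MHC class I genes H2-T18 and H2-T3 were higher on that array, at 609 and 590, against 14.4 to 37.2 and 42.9 to 52.2 on the others. On control replicate 1, Cap1, an actin regulator, had 80.3 against 905 to 1461.

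Several of the strongest changes lay near Atg16l1 in the gene order. Of 96 tested genes within 100 places of it, 3 (Ramp1, Stk25 and D2hgdh) had p under 0.001, multiplied by the gene's number of probe sets, against 56 of 10120 other genes (odds ratio 5.79, 95% confidence interval 1.14 to 18.3, one-sided Fisher's exact p 0.0179). Within 50 places it was 1 of 45 (exact p 0.230) and within 200 places 6 of 200 (odds ratio 5.81, exact p 0.000993), and Ramp1 was the only gene tested with probe sets past p 0.001 in opposite directions. Array brightness is argued against as the cause, since the odds ratio was 13.4 (95% confidence interval 1.48 to 58.3, exact p 0.0121) with quantile normalization, where 2 of 96 near genes and 16 of 10121 others were past the limit, whereas direction with the main settings differed with the window, with 2 of 3 lower within 100 places and 2 of 6 within 200. A candidate explanation is DNA of another strain that stayed linked to the mutated gene, but strain backgrounds are not given in the sources used here and an effect of Atg16l1 on its neighbours was not tested.

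Cell cycle genes lay above genes of like signal by a median log2 of 0.28 (95% bootstrap interval 0.20 to 0.36), and the 44 tested markers of dendritic cells, B cells and macrophages or granulocytes were at -0.31 (-0.44 to -0.20). These intervals resample genes with the arrays held fixed, so they leave out the spread between animals. From the brightness of the arrays within groups, 0.032 and -0.0083 were predicted, which argues against brightness as the cause of the cell cycle part (0.044 and -0.032 from the hypomorph and control pairs alone), while for the markers it stays open, since the pairs differed (0.046 and -0.29), a spread that the bootstrap over genes had left out. For double-negative thymocytes, 7 of their genes were at a median of -0.032 (-0.38 to 0.00093), below the cell cycle median, which gives no sign of a larger share. Such a share is not excluded, since the median of these genes differed by 0.15 between the hypomorph arrays and by -0.24 between the control arrays. Fewer antigen-presenting cells in the hypomorph suspensions may account for the lower markers, as 85.7% of dendritic cell and 90.9% of B cell genes lay below genes of like signal. Only 68.4% of macrophage and granulocyte genes did, but that list also holds granulocyte genes such as S100a8 and S100a9, which were low on control replicate 1. Whether antigen-presenting cells were fewer stays open, as does array brightness for these markers. An effect of the Atg16l1 allele on proliferation or on these cells is also open. None of these lists was called with an estimated correlation, but that setting could hardly call any list. Calls with the preset correlation do not measure the spread between animals.

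The probe sets that stood apart on 1 array formed 3 pairs of genes within 20 places of each other on the same array, against 0.730 in random draws (one-sided permutation p 0.0378), all 3 on hypomorph replicate 2 (0.672 in random draws, permutation p 0.0313) and 0 on each other array, so strain variants that this animal did not share are a candidate explanation for that array alone. Other cells in the hypomorph replicate 2 sample are argued against for the 34 of its 49 (69.4%) that were lower there, since added cells raise transcripts. For the 15 higher ones this stays open, because the filter on mean signal favours probe sets that are lower on 1 array. On each other array 100% were lower. Faulty hybridization of single probe sets stays open, since 35% of the other probe sets of these genes moved the same way by at least 1 on the log2 scale. Of the 3 splits of the 4 arrays into pairs, 3 gave at least 14 calls, the real one giving 14 and the highest other 88, and 3 splits are too few for a share under 0.05. That other split, hypomorph replicate 1 with control replicate 1, called 6 probe sets of sex-linked genes and 31 that stood apart on 1 array. It divides the arrays by their Xist and Y-linked signals, so its 88 calls do not show what a split without real differences would give. The remaining split, hypomorph replicate 1 with control replicate 2, does not divide the arrays by those signals and called 68, more than the real one. Of these, 0 were of sex-linked genes and 34 stood apart on 1 array. At an unadjusted p under 0.05 in limma the real split gave 3624 probe sets (1558 with quantile normalization) and the others 721 and 793 (quantile normalization not run for these). The fits had prior degrees of freedom of 8.95, 106 and 146.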
